A study of Mus musculus with 24 samples.

How the data were processed

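The series measured hippocampal messenger RNA in female mice of 2 strains on 3 diets. The 3xTg-AD line (3xTg) carries human APP and MAPT transgenes in a Thy1 expression cassette, and B6129SF2/J mice (WT) served as the comparison strain. Poly(A) libraries were made from 500 ng of total RNA with an RNA integrity number above 8 and 11 cycles of PCR. The labels name Trimmomatic, STAR and the GRCm38 genome for the step from reads to counts. The gene counter, the gene annotation and the tool that set the scaling factors are not given in the sources used here.

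The authors deposited 1 table of signal values, which are normalised read counts for 21793 genes in 24 libraries. Every value was a whole multiple of 1 step per library, within a tolerance of 0.01 reads, so each column equals whole reads divided by 1 factor and the whole reads were recovered from it. The ratio of DESeq2 median-ratio factors, computed from the recovered reads, to these factors lay between 1.05 and 1.06 in every library. By symbol, 21556 genes matched 1 gene of GENCODE release M21 on GRCm38. A further 27 symbols matched several genes and 210 matched none. The table also held 26 names altered to dates, of which 2 occurred more than once, and these genes carry no position here.

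Reads per library ranged from 2.65 M in 3xTg_K_2 to 25.8 M in 3xTg_M_2. Libraries are named by strain, diet (C control, K ketogenic, M medium-chain triglyceride) and replicate. PCR duplicates cannot be removed from a table of counts, so counting intervals would cover counting error alone, and all errors given here are spreads between mice. No pair of libraries was a copy of another: the lowest chi-square per degree of freedom between any 2 libraries was 1.61, and 2.09 within a group. Both values came from pairs with 3xTg_K_2, the library with the fewest reads. Among pairs without it the lowest was 3.15, and 3.60 within a group.

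Genes with a normalised count of 10 or more in at least 3 libraries were kept, which left 14162 genes, and 3695 genes were at 0 in every library. Log2 values after adding 1 were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 6 groups and a mean-dependent prior variance. Tests were two-sided with Benjamini-Hochberg adjustment over all kept genes, and a gene was called at an adjusted p under 0.05. The planned comparisons were genotype on the control diet, each diet within each genotype, each diet averaged over genotypes, ketogenic minus MCT, and the interaction of each diet with genotype. Tested on simulated data with the same group sizes, the fit recovered between 68% and 82% of genes changed 1.5-fold and between 92% and 100% of genes changed 2-fold, with 6 to 10 false calls among 13962 unchanged genes. In each simulation 50 genes were changed at each fold of 1.25, 1.5, 2 and 3. The changed genes had a mean of at least 32 normalised counts, reads were drawn for each gene independently and every label was correct. With that many changed genes the adjusted threshold is easier to pass, so these shares do not describe comparisons in which few genes change.

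A set of 37 gene lists covered the transgene loci, cell types of the hippocampus and of neighbouring tissue, synaptic and activity genes, and metabolic and stress pathways. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with camera at an estimated correlation and with fry. Fry results are those of its directional test, unless its mixed form, which lets members move either way, is named. Within a comparison, members were also adjusted over the list alone. The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. That rule took the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 32 normalised counts, leaving out predicted genes, or 5 and 5 for comparisons averaged over genotypes and for interactions. For the added comparison of genotypes averaged over diets, which the rule did not foresee, 10 and 10 were taken. Where fewer than 5 genes passed, it took the 5 with the smallest p, given as values. From a list it took up to 4 called members, or up to 2 members as values where none was called. App, Mapt and Thy1 were given in each genotype comparison.

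The levels of Thy1 in 3 libraries (3xTg_C_3, 3xTg_K_1 and WT_M_2) went against their genotype labels. All 24 libraries kept their labels in the results given first, and nothing was relabelled. A fit of the 21 other libraries, with 14126 genes kept, and a further comparison of the genotypes averaged over the 3 diets were added after this was seen. Within each of these fits the libraries of a group share 1 estimate of the spread with all other groups.

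The alternatives tried were pseudocounts of 0.5 and 5, no filter, a filter at a mean of 50, TMM factors, quantile normalisation, a fit of the compared groups alone, library weights, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. The ketogenic and MCT effects share their control libraries, so their overlap was set against 100 simulations of unchanged groups and, in WT, against split controls. Library pairs with equal replicate numbers were checked for shared deviations before the block was compared.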

Results

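RNA of the hippocampus was sequenced from 24 female mice, 12 of the 3xTg-AD line (3xTg), a model of Alzheimer's disease, and 12 of the B6129SF2/J strain (WT). From 3 months of age the mice ate 1 of 3 diets for 6 months. The control diet held 70% carbohydrate, 20% long-chain triglyceride and 10% protein at 4.1 kcal/g. In the MCT diet, 10% of medium-chain triglyceride took the place of long-chain fat, and the ketogenic diet held 90% long-chain triglyceride and 10% protein at 6.7 kcal/g. Groups held 3 (3xTg control), 5 (3xTg ketogenic) or 4 libraries (3xTg MCT and each of the WT groups). Reads assigned to genes ranged from 10.1 to 25.8 M per library, except for 3xTg_K_2 with 2.65 M. The first principal component held 22.8% of the variance and the second 12.3%. The shallow library 3xTg_K_2 lay apart from all others on both, at -42.2 and -48.5, where the others lay between -16.8 and 19.5 and between -7.27 and 11.1.

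Thy1 encodes a surface glycoprotein of neurons, and its promoter drives the transgenes of the 3xTg line. In 11 WT libraries the Thy1 normalised count lay between 6952 and 8137, and in 10 3xTg libraries between 20385 and 29277. The library labelled 3xTg_C_3 had 9189, the library labelled 3xTg_K_1 had 8112 and the library labelled WT_M_2 had 23048. App, the amyloid precursor gene, separated the same libraries. It was at 23524 in the library labelled 3xTg_C_3, 23019 in 3xTg_K_1 and 30297 in WT_M_2, against a group mean of 24213 ± 1041 (SD, n = 4) in WT control. On the first component these 3 libraries also lay with the other genotype, at 13.1, 11.7 and -16.5, where the other WT libraries were at 8.17 or above and the other 3xTg libraries at -9.46 or below. Results are given for all 24 libraries as labelled, and counts of genes that change with the 21 libraries left without these 3 are given beside them. Values for Thy1 and App without them are circular, since Thy1 picked them out and App separated the same libraries.

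**Figure D1:**
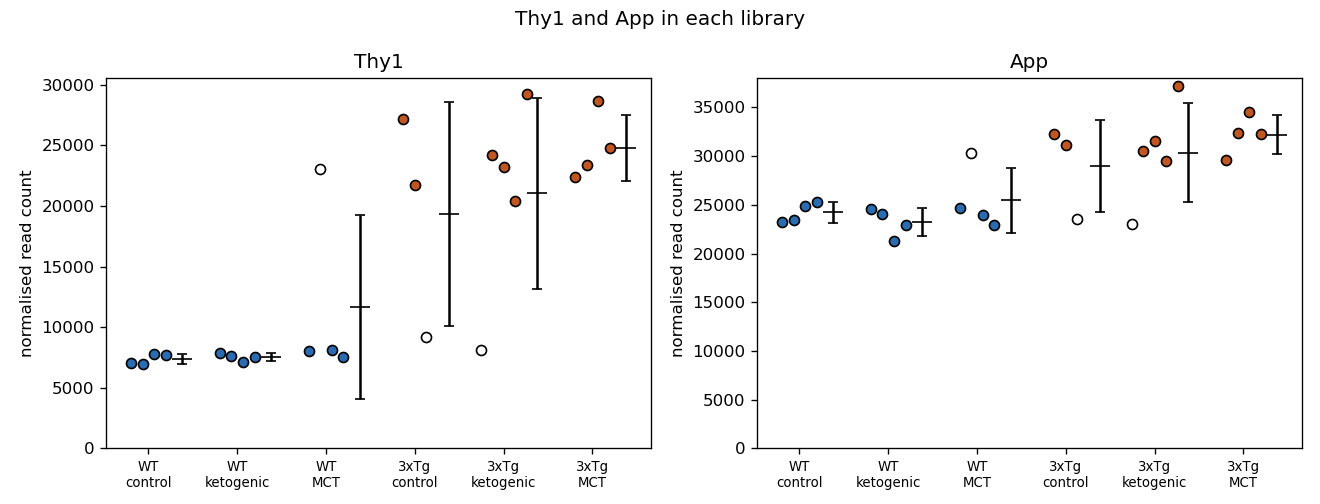
Normalised read counts of Thy1 (left) and App (right) in each library, by group, with WT libraries in blue, 3xTg libraries in orange and the 3 libraries whose Thy1 goes against their label as open circles. The bar beside each group is its mean ± SD over all its libraries, and the open circles for 3xTg control and ketogenic lie at 9189 and 8112 for Thy1.

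The comparison of genotypes on the control diet asks how the 3xTg hippocampus differs from WT without either test diet. Of 14162 genes, 8 were called, 1 higher and 7 lower in 3xTg. Zfp367, a zinc finger gene (chromosome 13, 64133018 to 64153202), was at 506 ± 35.8 (SD, n = 3) normalised counts in 3xTg and 362 ± 4.02 (n = 4) in WT, a log2 difference of 0.48 ± 0.09 (SE; adjusted p = 0.0348). Adam1a, a metalloprotease gene (chromosome 5, 121518576 to 121545482), was at 38.8 ± 9.23 against 78.7 ± 10.2, a log2 change of -1.02 ± 0.17 (adjusted p = 0.0292). Cemip, which acts in hyaluronan breakdown, fell by 0.47 ± 0.08, and the neuron navigator gene Nav1 fell by 0.63 ± 0.11. Ntng2, a synaptic adhesion gene, fell by 0.52 ± 0.09, Auts2 by 0.44 ± 0.08, the receptor gene Notch1 by 0.41 ± 0.08 and the acetyltransferase gene Kat6b by 0.30 ± 0.06. For each of these 8 genes, all 3 of the 3xTg libraries lay beyond all 4 WT libraries, the library labelled 3xTg_C_3 included. The genes were called for a difference in these same libraries, so this separation adds no support. Thy1 differed by 1.26 ± 0.36 (adjusted p = 0.128), App by 0.25 ± 0.12 (adjusted p = 0.336) and Mapt, the tau gene, by 0.07 ± 0.07 (adjusted p = 0.651). DESeq2 on all libraries called Thy1, at 1.39 (adjusted p = 0.0276). With the 3 libraries left out the count was 246 (117 higher and 129 lower), among them all 8 genes above. There Lgr6 rose by 2.05 ± 0.17 and Cdkn1a by 1.42 ± 0.28, and Mcm6 fell by 2.41 ± 0.18 (n = 2 against 4). The count was 0 without 3xTg_C_1, WT_C_1 or WT_C_2 and in a fit of the 2 groups alone, 4 without WT_C_3, 66 without 3xTg_C_3, 104 without 3xTg_C_2 and 220 with DESeq2. Zfp367 (adjusted p = 0.0611), Auts2 and Notch1 (0.0653 each) lost the call without WT_C_4, and Notch1 (0.0634) without 3xTg_C_3; over their alternatives the highest adjusted p of the 8 genes lay between 0.491 and 0.602.

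Of the 37 gene lists, 15 passed camera on the control diet, 9 higher and 6 lower in 3xTg, and 9 of the 15 kept the call whichever library was left out. The cholesterol synthesis and uptake list had 19 of 23 members higher in 3xTg, with a median log2 difference of 0.15 (camera adjusted p = 1.03e-05). None of its members passed over all genes, and 7 were higher when adjusted over the list alone; Sc5d, a late step of the pathway, was at 0.24 ± 0.05 (adjusted p = 0.0581) and Hmgcs1, an early one, at 0.44 ± 0.10 (adjusted p = 0.0974). This list had an adjusted p = 0.468 with an estimated correlation. The insulin and IGF signalling list had 11 of 15 members lower, 6 of them called when adjusted over the list alone and none over all genes, with Igf1r, the IGF1 receptor, at -0.35 ± 0.07 (adjusted p = 0.0533). Its camera adjusted p = 0.00219 became adjusted p = 0.468 with an estimated correlation. Among immediate early genes, which neurons switch on with activity, 16 of 18 were lower and the median was -0.39, with Fos at -0.88 ± 0.34 and Jun at -0.46 ± 0.18. That list had a camera adjusted p = 5.04e-05 and an adjusted p = 0.468 with an estimated correlation, and no member was called in either adjustment. In the nuclear oxidative phosphorylation list 40 of 43 members were higher with a median of 0.12 (camera adjusted p = 2.18e-08, adjusted p = 0.512 with an estimated correlation), and none was called over all genes or adjusted over the list alone. Cell type lists were called in the same comparison. Oligodendrocyte and myelin genes had 13 of 14 members higher with a median of 0.25 (camera adjusted p = 0.000194, adjusted p = 0.512 with an estimated correlation). GABAergic interneuron genes had 11 of 12 higher with a median of 0.15, and dentate gyrus granule cell genes 7 of 9 lower with a median of -0.21. Their camera adjusted p were 0.00219 and 0.00521, and both had an adjusted p = 0.468 with an estimated correlation. No member of these 3 lists passed over all genes, and 1, 3 and 4 did when adjusted over the list alone. Excitatory synapse genes (16 of 20 lower, median -0.07) and the mitochondrial genome (8 of 8 higher, median 0.20) also kept the call. Their camera adjusted p were 0.00219 and 0.000441, and both had an adjusted p = 0.468 with an estimated correlation. Homeostatic microglia, astrocyte, meningeal fibroblast, glucocorticoid response and cytosolic ribosome lists were called as well and lost the call without at least 1 library. These had an adjusted p = 0.468 to 0.709 with an estimated correlation. The choroid plexus list had all 10 members lower, with a median of -0.99, and its call ended without WT_C_1, where the adjusted p was 0.693. Its call also ended without 3xTg_C_1. No list was called in this comparison with an estimated correlation or with directional fry, and mixed fry called 3.

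Averaged over the 3 diets, a comparison added after the labels were checked, 1147 genes were called between genotypes, 526 higher and 621 lower in 3xTg. Among the highest in 3xTg were Stbd1, a glycogen-binding gene, at 160 ± 70.1 (SD, n = 12) against 46.3 ± 46.5 (n = 12) normalised counts, a log2 difference of 1.92 ± 0.41 (SE). The ribosomal protein gene Rpl34 rose by 1.89 ± 0.30 and Lgr6, a receptor of the R-spondin family of ligands, by 1.49 ± 0.29. The mitotic checkpoint gene Bub1b (1.44 ± 0.43), the ribosomal gene Rpl3 (1.38 ± 0.42), Zfp457 (1.35 ± 0.30), the complement inhibitor gene Cd59a (1.35 ± 0.26), Thy1 (1.29 ± 0.19), the actin-capping gene Capza1 (1.23 ± 0.20) and Spink8 (1.08 ± 0.20) were also higher. The largest fall was in Serpina3m, a serine protease inhibitor, at 13.4 ± 28.8 against 64.2 ± 29.2, a log2 change of -3.69 ± 0.72 (adjusted p = 0.00301), with 10 of 12 libraries below the WT mean. The tubulin gene Tuba1c fell by 3.29 ± 0.71, and the chemokine genes Ccl28 and Ccl27a fell by 2.40 ± 0.49 and dropped by 2.17 ± 0.45. Tagap (-1.94 ± 0.33), the protocadherin gene Pcdhga11 (-1.88 ± 0.34), the DNA replication gene Mcm6 (-1.73 ± 0.27), Pyroxd2 (-1.53 ± 0.23), the phospholipase gene Pla2g4e (-1.51 ± 0.35) and the collagen gene Col6a5 (-1.45 ± 0.30) were lower too. For the other 19 named genes, 10 to 12 of the 12 libraries of 3xTg lay on the called side of the WT mean, with adjusted p from 0.000442 to 0.0422. App rose by 0.32 ± 0.06 (adjusted p = 0.00326) and Mapt was at 0.06 ± 0.04 (adjusted p = 0.353). Close relatives can take each other's reads for Serpina3m, Tuba1c, Ccl27a, Pcdhga11, Rpl34 and Rpl3, and reads from the human transgenes may be counted in App, Mapt and Thy1. The count was 1858 without the 3 libraries, of which 1049 were shared in the same direction, and 576 without 3xTg_C_1. Bub1b and Rpl3 lost the call without any of several libraries, at an adjusted p of up to 0.104 and 0.0982 without 3xTg_C_1. They also lost it with no filter (0.0567 and 0.0635) and with the replicate block (0.0664 and 0.0616). Rpl3 lost it with DESeq2 (0.0597), and Pla2g4e with edgeR and DESeq2 (up to 0.0927).

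**Figure D2:**
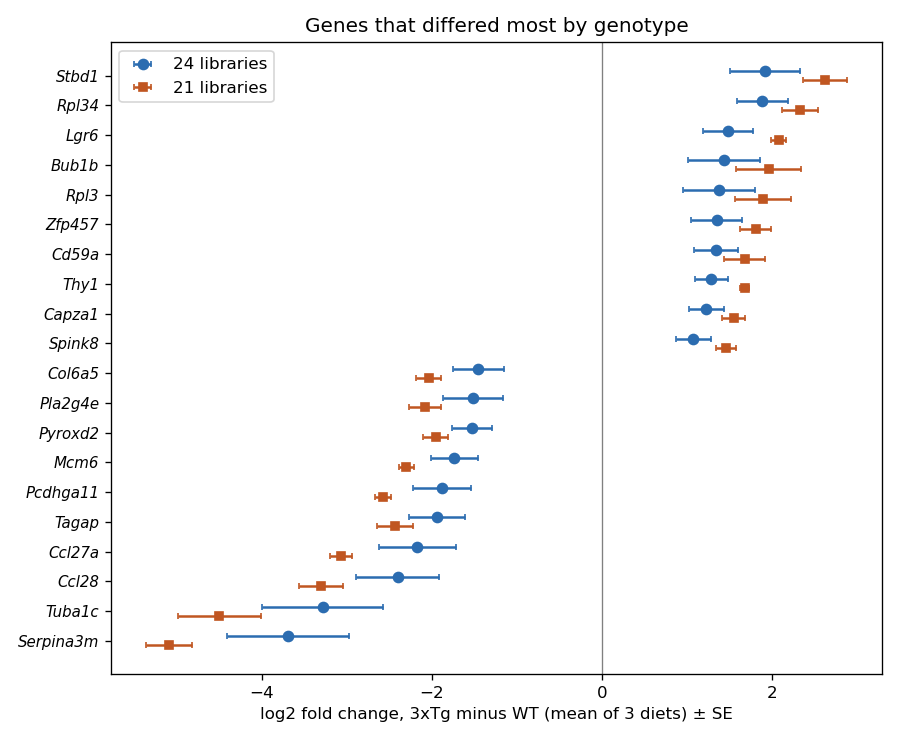
Log2 fold change between 3xTg and WT averaged over the 3 diets, with bars of ± SE, for the 10 called genes with the largest rise and the 10 with the largest fall, from all 24 libraries (circles) and from 21 libraries (squares). Serpina3m lies at -3.69 in the first and all 20 genes lie on the same side of 0 in both.

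In the lists averaged over diets, genes of dentate gyrus granule cells, the principal neurons of that subfield, were lower in 3xTg. The list had 6 of 9 members called lower over all genes and 6 adjusted over the list alone, with C1ql2, a secreted synaptic protein, down by a log2 change of -1.10 ± 0.15, Lct of -0.70 ± 0.10, and Prox1, the transcription factor of these cells, of -0.30 ± 0.05. Its camera adjusted p was 5.16e-06 and fry gave 0.00087, against an adjusted p = 0.209 with an estimated correlation. In the glucocorticoid response list 6 of 13 members rose over all genes and 11 adjusted over the list alone: Cdkn1a, a cell cycle inhibitor, by 0.74 ± 0.18, Tsc22d3 by 0.57 ± 0.14, the NF-kappaB inhibitor gene Nfkbia by 0.51 ± 0.12 and Txnip by 0.38 ± 0.10. Camera gave this list an adjusted p of 4.18e-06 and fry one of 0.0488, with an adjusted p = 0.483 with an estimated correlation. Cholesterol synthesis and uptake had 6 of 23 members called higher (7 adjusted over the list alone), led by Sc5d (0.19 ± 0.03) and Hmgcs1 (0.34 ± 0.05), with a camera adjusted p of 5.16e-06, fry at 0.019 and an adjusted p = 0.483 with an estimated correlation. Insulin and IGF signalling had 5 of 15 members called lower (6 adjusted over the list alone), among them Igf1r (-0.23 ± 0.04), the adaptor gene Irs1 (-0.27 ± 0.05) and Foxo1 (-0.18 ± 0.04), with a camera adjusted p of 0.00176, fry at 0.00389 and an adjusted p = 0.414 with an estimated correlation. GABAergic interneuron genes had 4 of 12 members called higher (5 adjusted over the list alone), among them Vip, a neuropeptide gene, by 0.45 ± 0.07 and Dlx1 by 0.25 ± 0.05, with a camera adjusted p of 0.00176, fry at 0.0259 and an adjusted p = 0.483 with an estimated correlation. Excitatory synapse genes had 6 of 20 called lower, with Shank3, a postsynaptic scaffold, at -0.32 ± 0.05 and Camk2a at -0.20 ± 0.05, and when adjusted over the list alone 6 were lower and 3 higher; its camera adjusted p was 0.00804, with fry at 0.0525 and an adjusted p = 0.614 with an estimated correlation. Of 11 lists called by camera, 7 kept the call whichever library was left out, these 6 and the immediate early list, in which Egr1 fell by 0.28 ± 0.07 (camera adjusted p = 7.42e-05, fry at 0.0525, adjusted p = 0.483 with an estimated correlation). The other 4 lost the call without at least 1 library. Oligodendrocyte and myelin (11 of 14, median 0.09), mitochondrial genome (8 of 8, 0.10) and interferon response genes (14 of 16, 0.18) were higher. Endothelial and mural genes (11 of 13, -0.08) were lower. Over all genes 3, 1, 0 and 2 members of these lists were called. Their camera adjusted p lay between 0.0292 and 0.0478, with an adjusted p = 0.679 to 0.682 with an estimated correlation. No list call held with an estimated correlation, in this or any other comparison.

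The ketogenic diet within WT asks what a diet of almost only fat does to the WT hippocampus. No gene was called with limma, edgeR or DESeq2 (0 each), and 654 genes had an unadjusted p under 0.05 where 708 would by chance. The 5 genes with the smallest p, given as values, were Neto1, an auxiliary glutamate receptor subunit, at -0.34 ± 0.08 (SE), Atpaf1 at -0.39 ± 0.09, Cep83 at 0.21 ± 0.05, Phactr2 at -0.40 ± 0.10 and Sec24d at -0.27 ± 0.07, with an adjusted p of 0.983 each and n = 4 in both groups. Ketone body metabolism and transport genes had 8 of 10 members higher with a median of 0.06, among them Oxct1, which activates ketone bodies, at 0.10 ± 0.04. None of the 10 was called over all genes or adjusted over the list alone, and the camera adjusted p of 0.0375 became an adjusted p = 0.529 with an estimated correlation. Of 8 lists called by camera (7 higher and 1 lower), none kept the call whichever library was left out. Among them, ependymal genes were lower in 7 of 7 (median -0.55, camera adjusted p = 0.00863). Oligodendrocyte and myelin genes were higher in 13 of 14 (0.11) and homeostatic microglia genes in 11 of 12 (0.10), at a camera adjusted p of 0.0375 each. All 3 had an adjusted p = 0.99 with an estimated correlation. That list count was 5 without WT_C_1 and 2 without WT_K_3.

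Within 3xTg, the ketogenic diet gave no called gene with limma, edgeR or DESeq2 (0 each), with 948 genes at an unadjusted p under 0.05. The smallest p belonged to Zswim6 (0.30 ± 0.07), the receptor phosphatase gene Ptpru (0.46 ± 0.11), Pkig (-0.35 ± 0.09), the vesicle fusion gene Vamp3 (-0.31 ± 0.08) and Nelfcd (-0.24 ± 0.06), each with an adjusted p of 0.724 (n = 5 against 3). Interferon response genes had 15 of 16 members higher on the diet, with a median of 0.59 and the antiviral gene Oasl2 at 1.36 ± 0.47. Camera gave this list an adjusted p of 4.05e-06, with an adjusted p = 0.704 with an estimated correlation, and none of its members was called over all genes or adjusted over the list alone. Immediate early genes had 16 of 18 members higher, with Fos at 0.85 ± 0.32 (camera adjusted p = 4.44e-05, adjusted p = 0.704 with an estimated correlation), and all 43 nuclear oxidative phosphorylation genes were lower, with a median of -0.08 (camera adjusted p = 2.49e-08, adjusted p = 0.716 with an estimated correlation). No member of either was called in either adjustment. Lists that moved the other way for genotype on the control diet are not independent reversals. Both comparisons use the same 3 control libraries of 3xTg, with opposite sign. The GABAergic interneuron list had 10 of 12 members lower, with the neuropeptide gene Npy at -0.54 ± 0.16 and 1 member called when adjusted over the list alone (camera adjusted p = 0.00436, adjusted p = 0.704 with an estimated correlation). These 4 lists, of 8 called, kept the camera call whichever library was left out, and without 3xTg_C_2 the count of genes was 1. Striatum genes, which would mark neighbouring tissue, had 7 of 9 members lower with a median of -0.31, 2 of them called when adjusted over the list alone (camera adjusted p = 0.00436, adjusted p = 0.565 with an estimated correlation). Oligodendrocyte and myelin genes had 13 of 14 lower with a median of -0.14 (camera adjusted p = 0.00227, adjusted p = 0.799 with an estimated correlation). Both lists lost the call without at least 1 library. So did complement and antigen presentation and cytosolic ribosome genes (adjusted p = 0.704 and 0.799 with an estimated correlation).

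The MCT diet within WT asks the same of a diet in which medium-chain fat takes the place of part of the long-chain fat. Eif3j2, a copy of a translation initiation factor gene (chromosome 18, 43475418 to 43477796), was the 1 gene called. It was at 1.44 ± 0.98 (SD, n = 4) normalised counts on MCT and 54.8 ± 17.0 (n = 4) on control, a log2 change of -4.59 ± 0.76 (SE; adjusted p = 0.042) whose size depends on the 1 added to counts this low. All 4 MCT libraries lay below all 4 control libraries. The gene fell outside the rule for naming and is given because no other passed. Pla2g4e (chromosome 2, 120166412 to 120245335), which the rule named as a value, was at 31.7 ± 7.74 on MCT against 277 ± 118 on control (log2 -3.04 ± 0.60, adjusted p = 0.163). Exd1 was at -1.38 ± 0.25 (adjusted p = 0.076), Hspa8, a heat shock chaperone, at 0.79 ± 0.19 (adjusted p = 0.697), Haus2 at 0.40 ± 0.10 (adjusted p = 0.697) and Mfap1b at 0.57 ± 0.14 (adjusted p = 0.94). Eif3j1, the parent gene of Eif3j2 with which it can exchange reads, was chosen after its values were seen and was at 156 ± 12.5 on MCT against 68.5 ± 29.5 on control (log2 1.32 ± 0.53, adjusted p = 0.989). Eif3j2 lost its call without any 1 of the 8 libraries of both groups, at an adjusted p of 0.173 (without WT_C_1), 0.322 (WT_C_2), 0.228 (WT_C_3), 0.0563 (WT_C_4), 0.139 (WT_M_1), 0.125 (WT_M_2), 0.0882 (WT_M_3) or 0.0598 (WT_M_4), and with edgeR (0.319). Over all its alternatives its adjusted p ran from 2.04e-05, without the 3 libraries, to 0.322. Leaving out the 3 libraries gave 3 genes, Eif3j2, Pla2g4e (adjusted p = 2.57e-05) and Fam227b (adjusted p = 0.0133), all lower; at an unadjusted p under 0.05 there were 679 genes with all libraries.

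**Figure D3:**
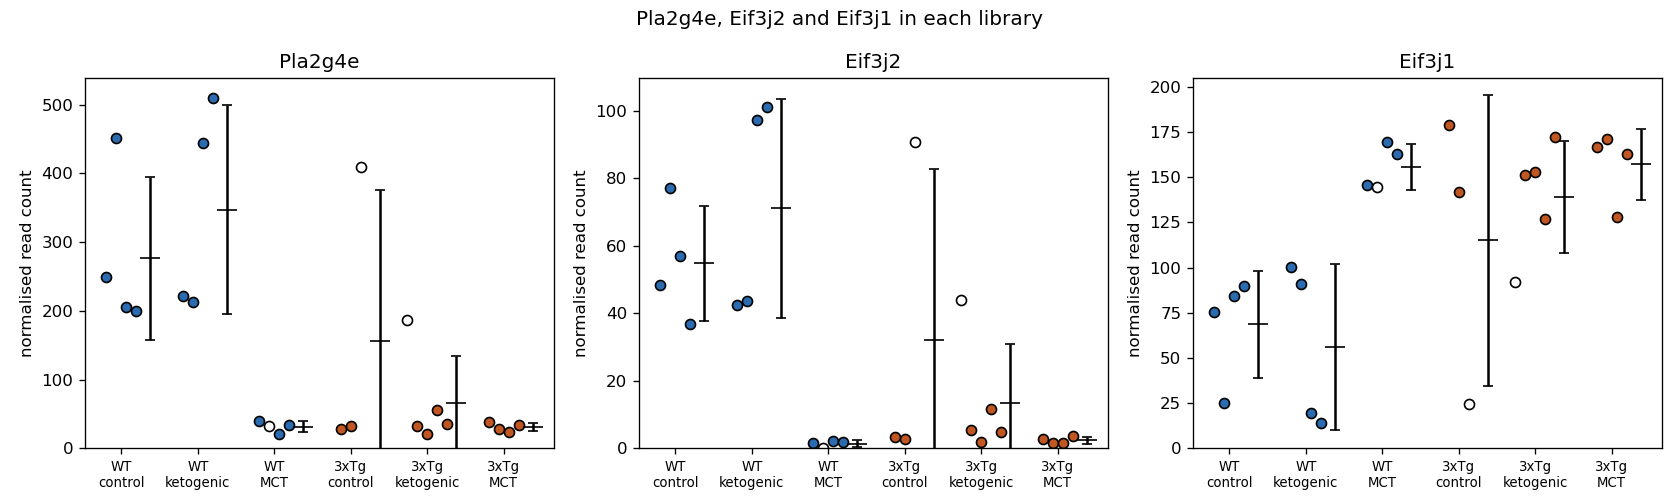
Normalised read counts of Pla2g4e, Eif3j2 and Eif3j1 in each library, by group, with WT in blue, 3xTg in orange and the 3 libraries whose Thy1 goes against their label as open circles; bars give the mean ± SD of each group. All 4 WT MCT libraries lie at 39.4 or less for Pla2g4e and the other 8 WT libraries between 200 and 510.

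Of 10 lists called by camera for MCT in WT, 4 kept the call whichever library was left out. Neocortex genes, which would mark tissue from outside the hippocampus, had 8 of 9 members lower, with Rorb at -0.19 ± 0.08 and Rspo1 at -0.80 ± 0.36 (camera adjusted p = 0.000343, adjusted p = 0.165 with an estimated correlation). Genes of meningeal fibroblasts, the cells of the brain's covering, had all 10 members lower, with a median of -0.57 and Lum at -0.45 ± 0.22 (camera adjusted p = 0.000335, adjusted p = 0.576 with an estimated correlation). The mitochondrial genome list had 7 of 8 members higher, with mt-Nd4 at 0.21 ± 0.08 (camera adjusted p = 0.000346, adjusted p = 0.576 with an estimated correlation). Unfolded protein response genes had 14 of 15 members higher, with the chaperone gene Hsp90b1 at 0.16 ± 0.07 (camera adjusted p = 0.000335, adjusted p = 0.629 with an estimated correlation). No member of these 4 lists was called over all genes or adjusted over the list alone. The choroid plexus list, markers of the tissue that makes cerebrospinal fluid, had all 10 members lower with a median of -1.25, and without WT_C_1 the median was -0.27 and the adjusted p 0.53. Astrocyte (camera adjusted p = 0.00134) and homeostatic microglia genes (0.037) each had 10 of 12 members higher with a median of 0.08. These calls were lost without at least 1 library and had an adjusted p = 0.576 and 0.629 with an estimated correlation. The list count was 17 without WT_M_3.

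Within 3xTg, the MCT diet gave no called gene with limma, edgeR or DESeq2 (0 each), and 378 genes had an unadjusted p under 0.05. The smallest p belonged to Ptpru (0.43 ± 0.12), the sodium-proton exchanger gene Slc9a2 (0.42 ± 0.12), Tsc2, a brake on mTOR signalling (0.22 ± 0.07), Kdm2b (0.28 ± 0.08) and Adamts17 (0.47 ± 0.14), with an adjusted p of 0.999 each (n = 4 against 3). Cytosolic ribosome genes had 29 of 31 members lower, with a median of -0.12 and Rpl38 at -0.23 ± 0.10 (camera adjusted p = 3.79e-06, adjusted p = 0.57 with an estimated correlation). Nuclear oxidative phosphorylation genes had 42 of 43 members lower with a median of -0.06 (camera adjusted p = 1.55e-07), and oligodendrocyte and myelin genes 13 of 14 with a median of -0.16 and Cnp at -0.31 ± 0.12 (camera adjusted p = 3.79e-06). Both had an adjusted p = 0.57 with an estimated correlation. These 3 lists, of 8 called, kept the call whichever library was left out, and none of their members was called over all genes or adjusted over the list alone. Here too the 3xTg control libraries also enter genotype on the control diet with opposite sign, so opposite list changes are not independent. The glucocorticoid response list, with 12 of 13 members higher and a median of 0.36, lost its call without the library labelled 3xTg_C_3 (median 0.03, adjusted p = 0.687). Striatum (median -0.26, camera adjusted p = 0.00826) and dentate gyrus granule cell genes (-0.09, 0.0437) each had 6 of 9 members lower. Both lost the call without at least 1 library and had an adjusted p = 0.57 with an estimated correlation. The list count was 13 without 3xTg_C_1 and 14 without 3xTg_M_3.

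**Figure D4:**
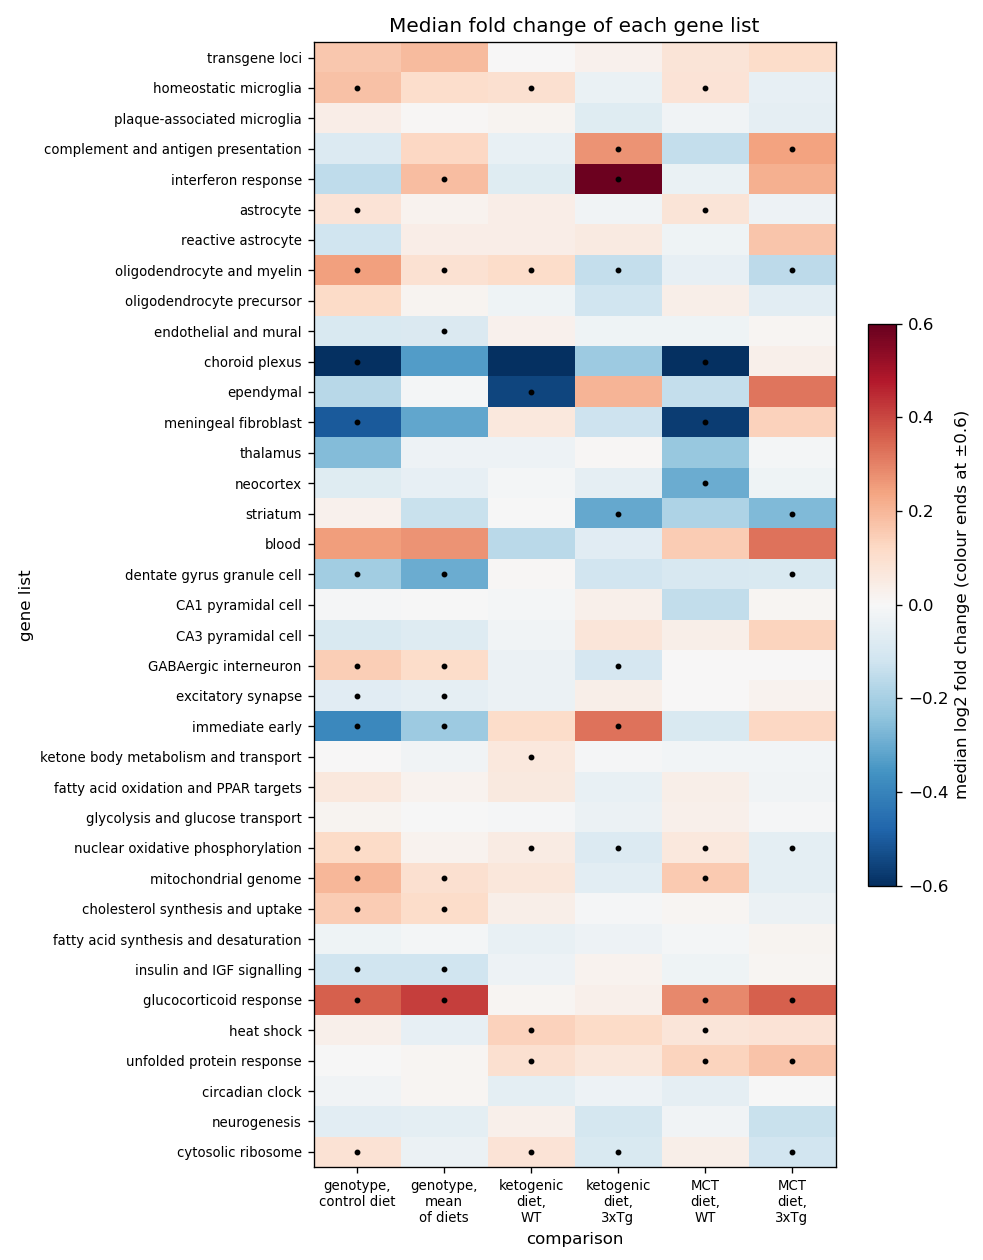
Median log2 fold change of the measured members of each of the 37 gene lists (vertical axis) in 6 comparisons (horizontal axis), with all 24 libraries as labelled, red for higher and blue for lower. A dot marks an adjusted p under 0.05 by camera with its preset correlation; with an estimated correlation no list passed in any of these comparisons.

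Averaged over both genotypes, the ketogenic diet gave no called gene with limma, edgeR or DESeq2 (0 each), and 706 genes had an unadjusted p under 0.05. Ppp1r3c, a glycogen-targeting subunit of a phosphatase, was at 0.27 ± 0.06 (SE), Nelfcd at -0.17 ± 0.04, Fastkd2 at 0.18 ± 0.05, the lipid transfer gene Pltp at -0.29 ± 0.08 and Bcam at -0.44 ± 0.12, with an adjusted p of 0.946 each (n = 9 against 7). Heat shock genes had 11 of 12 members higher with a median of 0.14 (camera adjusted p = 0.000978, adjusted p = 0.645 with an estimated correlation), and immediate early genes 16 of 18 with a median of 0.23 (camera adjusted p = 1.39e-05, adjusted p = 0.645 with an estimated correlation). Striatum genes (7 of 9 lower, median -0.15, camera adjusted p = 0.0347) and GABAergic interneuron genes (11 of 12 lower, -0.07, 0.00664) were called too. Both had an adjusted p = 0.645 with an estimated correlation and lost the call without at least 1 library. The MCT diet averaged over genotypes gave 0 called genes with limma, 1 with edgeR and 2 with DESeq2, and 601 genes had an unadjusted p under 0.05. Pla2g4e was at -2.13 ± 0.44 (adjusted p = 0.437), the leucine breakdown gene Ivd at 0.31 ± 0.08, Rasgef1b at -0.54 ± 0.15, Haus2 at 0.26 ± 0.07 and Khdrbs3 at 0.16 ± 0.04, the last 4 with an adjusted p of 1 (n = 8 against 7). Unfolded protein response genes had 13 of 15 members higher with a median of 0.15 (camera adjusted p = 1.72e-08, adjusted p = 0.519 with an estimated correlation). All 12 heat shock genes were higher, 1 of them called when adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.00209, adjusted p = 0.701 with an estimated correlation). Glucocorticoid response genes had 11 of 13 members higher with a median of 0.23 (camera adjusted p = 4.99e-05, adjusted p = 0.701 with an estimated correlation). Striatum genes were lower in 7 of 9 (median -0.25, camera adjusted p = 0.00263, adjusted p = 0.238 with an estimated correlation). Oligodendrocyte and myelin genes were lower in 12 of 14 (median -0.11, camera adjusted p = 0.000672, adjusted p = 0.734 with an estimated correlation). These 5 lists, of 8 called, kept the call whichever library was left out. Of the 5, glucocorticoid response, striatum, and oligodendrocyte and myelin lost it once the 3 libraries were left out together. Neocortex (9 of 9 lower, median -0.13), choroid plexus (10 of 10, -0.49) and dentate gyrus granule cell genes (7 of 9, -0.09) lost the call without at least 1 library. They lost it without the 3 libraries as well. Their camera adjusted p were 0.00329, 0.00643 and 0.0206, with an adjusted p = 0.238, 0.734 and 0.701 with an estimated correlation. Pla2g4e and Eif3j2 were called once the 3 libraries were left out, and without 3xTg_C_1 or 3xTg_C_2 the count was 1.

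Set against each other directly, the ketogenic and MCT diets differed in 1 called gene, Eif3j2, at 39.1 ± 38.2 (SD, n = 9) normalised counts on the ketogenic diet and 1.93 ± 1.06 (n = 8) on MCT, a log2 difference of 3.18 ± 0.53 (adjusted p = 0.0403). The difference came mainly from WT (71.0 against 1.44), with 13.5 against 2.43 in 3xTg and 5.98 against 2.43 there without the 3 libraries. All 9 ketogenic libraries lay above the MCT mean and 8 of them above all 8 MCT libraries, and 673 genes had an unadjusted p under 0.05. Given as values, Pla2g4e was at 1.99 ± 0.41 (adjusted p = 0.465), and D16Ertd472e (0.26 ± 0.06), the kinase gene Plk3 (0.31 ± 0.08), Zfp458 (0.31 ± 0.08) and Zfp420 (0.22 ± 0.06) had an adjusted p of 0.981. Immediate early genes had 16 of 18 members higher on the ketogenic diet, with a median of 0.19, and glucocorticoid response genes 11 of 13 lower, with a median of -0.25. Both had a camera adjusted p of 8.93e-05 and an adjusted p = 0.69 with an estimated correlation, and none of their members was called. Of the 8 other lists called, none kept the call whichever library was left out. Among them, oligodendrocyte and myelin (13 of 14, median 0.09), neocortex (8 of 9, 0.09) and CA1 pyramidal cell genes (6 of 7, 0.08) were higher. GABAergic interneuron (11 of 12, -0.06) and blood genes (5 of 5, -0.38) were lower. The camera adjusted p of these 5 lay between 0.018 and 0.0485, with an adjusted p = 0.69 to 0.785 with an estimated correlation. The call of Eif3j2 ended without any 1 library of the 4 groups other than 3xTg_K_3, with adjusted p from 0.0532 without 3xTg_K_1 to 0.176 without WT_K_4, and over all alternatives its adjusted p ran from 6.25e-05 to 0.215. The count of genes was 2 without the 3 libraries. The list count of 10 was 6 without 3xTg_K_2, 5 without 3xTg_M_2, WT_K_4 or WT_M_1, and 3 without 3xTg_M_4.

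Whether a diet acted differently by genotype was tested as an interaction. For the ketogenic diet no gene was called with limma, edgeR or DESeq2 (0 each), with 946 genes at an unadjusted p under 0.05. The smallest p belonged to the cilia gene Cfap44 (0.96 ± 0.22), Neto1 (0.46 ± 0.11), Itgbl1 (1.02 ± 0.25), Mrpl36 (-0.48 ± 0.13) and Polr2j (-0.40 ± 0.11), each with an adjusted p of 0.724. For the MCT diet no gene was called with any of the 3 tools (0 each), with 393 genes at an unadjusted p under 0.05, and the smallest p belonged to Exd1 (1.59 ± 0.37), Cox14 (-0.34 ± 0.10), Setd5 (0.31 ± 0.09), Vwa5b1 (1.10 ± 0.33) and Notch1 (0.36 ± 0.11), with an adjusted p of 1 each. For MCT 2 genes were called without the 3 libraries, Pla2g4e (3.05 ± 0.49) and Eif3j2 (3.94 ± 0.65), each with an adjusted p of 0.0267. In that fit 3xTg on control diet was at 30.7 and 3.02, as low as 3xTg on MCT (31.0 and 2.43) and WT on MCT (31.6 and 1.92). The interaction thus restates that WT on control diet stood above these groups. That is the MCT difference within WT as much as the genotype difference on the control diet. Camera called 7 lists for the ketogenic interaction and 10 for the MCT interaction, and none passed with an estimated correlation, where the lowest adjusted p were 0.717 and 0.564.

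The ketogenic and MCT effects were compared with each other across genes, and with the genotype difference, to see whether a diet moved genes that differ by genotype back towards WT. Across 14162 genes, which are not independent replicates, the effects of the diets correlated at r = 0.46 in WT and 0.54 in 3xTg. Both diets share the control libraries. Unchanged groups that share a control group, simulated by shuffling the deviations of all libraries from their group means, gave r = 0.51 and 0.60. The covariance was 0.018 in WT against a simulated 0.0201 (0.0085 to 0.038), and 0.0209 in 3xTg against 0.025 (0.0124 to 0.0586). With separate WT control libraries for each diet, in 6 ways, the covariance was 0.00142 on average (-0.00435 to 0.00404) and r = 0.03 (-0.07 to 0.08), ranges that include 0; in 3xTg the 3 control libraries could not be split with 2 in each part. The diet effect in 3xTg and the genotype difference on control diet use the same 3xTg control libraries with opposite sign. Their covariance was -0.0154 for the ketogenic diet against a simulated -0.0249 (-0.0574 to -0.0104), and -0.00663 for MCT against -0.0242 (-0.0568 to -0.00874), so neither was more negative than unchanged groups give, and the MCT value lay outside its simulated range on the less negative side. That ended without the 3 libraries (-0.0249 in -0.091 to -0.0149) and with a strict filter (-0.00277 in -0.0197 to -0.00261), and the value was -0.0251 without 3xTg_C_3 and -0.0217 without 3xTg_C_2. No gene was called for both diets in either genotype (0 of 0 and 1 in WT).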

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

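All tests in this part were chosen after the results were seen, apart from the interactions and the gene lists, which were planned.

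Thy1 was at 23048 in the library labelled WT_M_2, far from the other 3 libraries of its group (7570 to 8137), and Zfp367 was at 509 there. For Thy1, the libraries labelled 3xTg_C_3 and 3xTg_K_1 also lay on the side of the other genotype. For Zfp367 they did not. The lowest 3xTg control library was at 465 and the lowest 3xTg ketogenic one at 413, where WT libraries other than WT_M_2 reached 386 at most. Zfp367 was called on the control diet with 3xTg_C_3 as labelled, so for that library it is no independent check. Over genes that differed at least 2-fold between genotypes in the other 21 libraries, on a scale where WT is at 0 and 3xTg at 1, 3xTg_C_3 and 3xTg_K_1 stood at 0.03 and 0.03 and WT_M_2 at 1.02, at most 0.0334 from the genotype opposite to their labels. RNA of both strains mixed in similar amounts is argued against, since on the linear scale the nearest of them was 0.444 from the middle, and so is a transgene switched off or on, since 0 of the 3 lay nearer to their labelled genotype over genes outside the transgene loci. Over all called genes, many of them weak, the 3 stood at 0.23, 0.41 and 0.92, against -0.07 to 0.32 in WT and 0.67 to 1.11 in 3xTg, so 3xTg_K_1 lay between the ranges there. A wrong genotype label may account for the pattern (0.0334), but 2 libraries go one way and 1 the other, so a single exchange does not explain it, their diets stay open and an undetected exchange within a genotype was not tested.

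The larger genotype differences lay close together on the chromosomes, and so did genes with the smallest p for MCT in WT. Of the 70 genes that differed at least 2-fold between genotypes and had a position, 41.4% had another such gene within 1 Mb, against 10.6% in random draws (highest of 1000 draws 31.4%), whereas over all genotype calls the share was 73.1% against 72.2% and lay within the draws. For MCT in WT, 6 of the 20 genes with the smallest p lay within 10 Mb of each other on chromosome 2. That number was reached by 1 of 10000 random draws. With all libraries as labelled none of the 6 was called, and Eif3j2, the called gene, is on chromosome 18. Pla2g4e and Fam227b, both among the 6, were called once the doubted libraries were left out. Pla2g4e split the 8 other WT libraries. WT_C_2, WT_K_3 and WT_K_4 had 444 to 510 with Eif3j1 at 13.8 to 25.2, and the other 5 had 200 to 250 with Eif3j1 at 75.2 to 100. The MCT libraries had at most 39.4 with Eif3j1 at 145 to 169. Eif3j2 was at 77.0 to 101 in the first 3, 36.7 to 57.0 in the other 5 and at most 2.10 on MCT. Since Eif3j2 and Eif3j1 can exchange reads, the place of Eif3j2 on chromosome 18 does not set its call apart from this pattern. Strain variants inherited together may therefore underlie the larger genotype differences (41.4%) and the MCT values of the chromosome 2 neighbours (6), which were uncalled as labelled. The WT strain is a hybrid in which parental segments differ between mice. Families of neighbouring related genes would also raise these shares. The low level of Pla2g4e also occurred off MCT, in 5 of the 6 libraries of 3xTg mice on the other diets once the doubted ones were left out, with means of 30.7 (control) and 36.2 (ketogenic) against 31.6 in WT on MCT; in WT all mice with it ate MCT, so for them an effect of the diet and a shared segment cannot be told apart.

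Ttr, which encodes the transthyretin of choroid plexus, was at 11390 in WT_C_1 and 3921 in WT_K_1, with 286 as the highest of the other WT control libraries and 380 in the library labelled 3xTg_K_1, far from its own group (at most 107). All 10 measured choroid plexus genes were highest in WT_C_1 among the WT control libraries, Clic6 among them at 393 against at most 27.3 in libraries other than WT_C_1 and WT_K_1. Depth is argued against, since WT_C_1 had 15.4 M reads, within the range of its group, and so is an effect of the control diet, since Ttr stayed at 286 or below in the other 3 libraries on it. Choroid plexus tissue dissected with the hippocampus of this mouse is a candidate explanation (10 of 10 genes). The choroid plexus list lost its calls in comparisons with WT control when this library was left out. For genotype on the control diet the call also ended without 3xTg_C_1. For MCT averaged over genotypes it also ended without 3xTg_C_2 and without the 3 doubted libraries.

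Of 80 groups of values tested for a library far from its group, 11 held one, where chance gives about 5%. The genes tested were those reported above, among them Thy1, Ttr, Pla2g4e and Eif3j2, in which single libraries already stood out. The same libraries recur among the 11, so this count is no test against chance. Besides those given earlier in this part, the flagged values were 2.65 M reads in 3xTg_K_2 and 10.1 M in WT_C_2, Eif3j2 at 43.8 and Pla2g4e at 187 in the library labelled 3xTg_K_1, Adam1a at 63.6 in WT_C_3 and Kat6b at 1199 in WT_C_2.

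The effect of the ketogenic diet differed by genotype for 7 lists by camera, each value being the median log2 difference of the diet effect in 3xTg from that in WT. Higher were interferon response (0.65), ependymal (0.73) and excitatory synapse genes (0.0769), and lower were homeostatic microglia (-0.16), oligodendrocyte and myelin (-0.24), nuclear oxidative phosphorylation (-0.13) and cytosolic ribosome genes (-0.15). For the MCT diet 10 lists differed, with choroid plexus (1.15), meningeal fibroblast (0.79) and immediate early genes (0.26) higher. Lower were homeostatic microglia (-0.13), astrocyte (-0.12), oligodendrocyte and myelin (-0.14), nuclear oxidative phosphorylation (-0.13), mitochondrial genome (-0.21), cholesterol synthesis and uptake (-0.0889) and cytosolic ribosome genes (-0.15). Leaving out 1 library ended 3 of the 7 ketogenic calls, homeostatic microglia (adjusted p up to 0.316), ependymal (0.0657) and excitatory synapse genes (0.243). It ended 5 of the 10 MCT calls, choroid plexus (0.524, without WT_C_1), homeostatic microglia (0.455), cholesterol synthesis and uptake (0.445), oligodendrocyte and myelin (0.279) and immediate early genes (0.279), and none of the 17 calls held with an estimated correlation. Once the 3 libraries were left out, the MCT effect differed by genotype for Pla2g4e (3.05) and Eif3j2 (3.94). In 3xTg the control diet was already as low (30.7 and 3.02) as MCT (31.0 and 2.43). Pla2g4e thus showed no fall on MCT in 3xTg, and Eif3j2 was too low there for one to be seen.

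Other splits of the same libraries were used to see whether chance can be excluded for each count. It was excluded for the 1147 genes that differed by genotype averaged over diets, a count reached by 1 of 100 splits, the real one, with 1 gene in the highest other. Chance was not excluded for the 8 genes on the control diet (2 of 35 splits, highest other 9), for the 1 gene of MCT in WT (2 of 35, highest other 2) or for the 1 gene of ketogenic minus MCT (6 of 100, highest other 1). A count of 0 is reached by any split, so nothing is tested about chance there: 35 of 35 for the ketogenic diet in WT (highest other 1), 56 of 56 in 3xTg (117), 35 of 35 for MCT in 3xTg (0), and 100 of 100 for the ketogenic diet (58) and MCT (42) averaged over genotypes and for their interactions with genotype (4 and 63). The 117 genes came from the split that put the library labelled 3xTg_K_1 with 3xTg_C_1 and the library labelled 3xTg_C_3. This split was picked for its count, so it may reflect that these 2 labelled libraries are alike, and it shows no more than that the diet grouping is not the one with the most calls.

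For counts of lists, chance was not excluded in any comparison. As many lists as the real 15 for genotype on the control diet came from 3 of 35 splits (highest other 16), and as many as 11 averaged over diets from 23 of 100 (19). The ketogenic counts were reached by 19 of 35 splits in WT (8 lists, highest other 16), 23 of 56 in 3xTg (8, 15) and 75 of 100 averaged over genotypes (6, 17). The MCT counts were reached by 20 of 35 splits in WT (10 lists, highest other 17), 23 of 35 in 3xTg (8, 14) and 62 of 100 averaged over genotypes (8, 18). For ketogenic minus MCT it was 29 of 100 (10, 16), and for the interactions with genotype 56 of 100 for the ketogenic diet (7, 16) and 38 of 100 for MCT (10, 17).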

How the results depend on the processing

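Leaving out the 3 libraries, the further comparison averaged over diets with its settings, leaving single libraries out of the list and covariance results, and those tests were chosen after the data were seen; the other settings were planned. No single gene, list or left-out-library covariance changed sign. Of the 6 ways to split the WT controls, some did, with covariances of the diet effects from -0.00435 to 0.00404. With 1 library left out, 109 of 141 gene counts, 129 of 141 list counts and 40 of 47 covariances stayed near the value of the first fit, within 1.5 times for counts and within 1 SD of the simulated covariance. Of single genes 564 of 661 kept their side of the threshold, and of single list calls 1047 of 1281 held, against 268 of 505 under the other settings. Where no cause is given, the cause was not tested.

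The count of 8 genes for genotype on the control diet was 13 with a strict filter, 13 with library weights, 0 with only the 2 groups compared, 220 with DESeq2 and 246 without the 3 libraries. For MCT in WT the count of 1 was 0 with a pseudocount of 5, a strict filter (which removes Eif3j2), quantile normalisation or edgeR, 2 with the compared groups alone, and 3 with no filter, with DESeq2 or without the 3 libraries. For ketogenic minus MCT the count of 1 was 0 with a pseudocount of 5, with no filter, with a strict filter or with edgeR, and 2 with the compared groups alone, with DESeq2 or without the 3 libraries. Without a filter the counts of 0 became 2 for the ketogenic diet in WT, and 1 each for the ketogenic diet in 3xTg, MCT in 3xTg and the ketogenic diet averaged over genotypes. MCT averaged over genotypes went from 0 to 1 with edgeR, 2 with DESeq2 and 2 without the 3 libraries, and its interaction with genotype from 0 to 2 without them. The other counts of 0 stayed at 0 without the 3 libraries, with an unadjusted p under 0.05 for 698 (ketogenic diet in WT), 921 (in 3xTg), 731 (averaged), 931 (by genotype) and 165 genes (MCT in 3xTg). The 1147 genes of the genotypes averaged over diets became 1797 with library weights and 1858 without the 3 libraries.

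Replicate numbers did not pair the libraries: pairs with the same number had a mean correlation of 0.00608 (n = 55) and only 6 of 24 libraries correlated best with their own number. With the replicate block the count was 5 for genotype on the control diet, 0 for MCT in WT and 0 for ketogenic minus MCT, and the block moved no other gene count by over 1.5 times.

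With all 24 libraries, every count of lists became 0 with an estimated correlation and with directional fry, except 5 with fry for the genotypes averaged over diets. Without the 3 libraries directional fry called 1 list for genotype on the control diet and 12 averaged over diets. Mixed fry called 3 lists for genotype on the control diet and 17 averaged over diets. Without the 3 libraries it called 11 and 24, and in the diet comparisons it called none. With the 3 libraries left out, camera at its preset correlation called 3 lists for MCT averaged over genotypes and 11 for the ketogenic interaction. The covariance of the diet effects in WT was 0.00713 with the strict filter and 0.00142 with split controls. Leaving the 3 libraries out, the covariance with the genotype difference was -0.0282 for the ketogenic diet and -0.0249 for MCT, against simulated values of -0.0362 and -0.0343.

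Leaving out each library in turn, counts of genes ran from 0 to 104 for genotype on the control diet, 576 to 1511 averaged over diets, and 0 to 1 for the ketogenic diet in 3xTg, MCT in WT, MCT averaged over genotypes and ketogenic minus MCT. Counts of lists ran from 11 to 18 for genotype on the control diet and 7 to 16 averaged over diets. For the ketogenic diet they ran from 2 to 9 in WT, 6 to 11 in 3xTg and 4 to 9 averaged, and for MCT from 7 to 17 in WT, 6 to 14 in 3xTg and 7 to 11 averaged. They ran from 3 to 12 for ketogenic minus MCT and from 5 to 10 and 7 to 13 for the ketogenic and MCT interactions. The covariance of the diet effects ran from 0.0162 to 0.0267 in WT, highest without WT_C_3, and from 0.0185 to 0.0423 in 3xTg, highest without 3xTg_C_2. That with the genotype difference ran from -0.0386 to -0.00914 for the ketogenic diet and from -0.0251 to -0.00273 for MCT, lowest without 3xTg_C_3 for both. With 2 libraries left in 3xTg control, the fit takes their spread to be like that of the other groups. With 2.65 M reads in 3xTg_K_2, genes of low count are measured there with the least precision.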

Other observations

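Other genes of the fixed lists differed between genotypes averaged over the 3 diets, and their fit without the 3 libraries was chosen after the data were seen. Among reactive astrocyte genes 2 of 12 rose and 1 fell over all genes. Gfap, the intermediate filament of astrocytes, rose by 0.24 ± 0.05 (SE, n = 12 in each genotype, adjusted p = 0.00938), while Serpina3n, a serine protease inhibitor of reactive astrocytes, was lower by a log2 change of -1.30 ± 0.28 (adjusted p = 0.00526). The Serpina3n difference is above 2-fold, the range in which strain variants inherited together may underlie genotype differences. Whether Serpina3n exchanges reads with relatives, as Serpina3m can, was not tested. Among plaque-associated microglial genes 4 of 19 fell and none rose over all genes, with Lyz2 at -0.59 ± 0.17 and Gpnmb at -0.48 ± 0.15, whereas 3 of 12 homeostatic microglial genes rose, with Tmem119 at 0.30 ± 0.08. In the complement and antigen presentation list 3 of 14 rose, the complement genes C1qa (0.26 ± 0.07), C4b (0.40 ± 0.12) and C1qb (0.25 ± 0.08). These 4 lists did not pass camera, with adjusted p of 0.54, 0.587, 0.077 and 0.0641. Without the 3 libraries Gfap was at 0.27 ± 0.05, Serpina3n at -1.84 ± 0.12, Lyz2 at -0.81 ± 0.16, Gpnmb at -0.75 ± 0.09 and C4b at 0.58 ± 0.09.

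In the same comparison of genotypes, 1 of 10 ketone body metabolism and transport genes rose and 2 fell over all genes in 3xTg, and 4 and 2 did when adjusted over the list alone, with the monocarboxylate transporter gene Slc16a1 at -0.45 ± 0.10 (adjusted p = 0.00526). Pdk4, which restrains glucose oxidation, rose by 0.58 ± 0.17 (adjusted p = 0.0357), and Cox7c, a respiratory chain subunit gene, was lower by a log2 change of -0.61 ± 0.17 (adjusted p = 0.0246). Their lists did not pass camera in this comparison: fatty acid oxidation and PPAR targets had 1 of 24 members called higher and none lower (adjusted p = 0.531), and nuclear oxidative phosphorylation 2 of 43 higher and 1 lower (adjusted p = 0.0866). Gabra2, a GABA receptor subunit gene outside the lists and chosen after its values were seen, rose by 0.73 ± 0.19 (adjusted p = 0.0212), and by 1.08 ± 0.12 without the 3 libraries. For the ketone body list itself camera gave an adjusted p of 0.878.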
